A study of Mus musculus with 8 samples.

How the data were processed

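Gene expression was measured by RNA sequencing in 8 libraries made from mouse dorsal root ganglia, 4 with the genotype label WT and 4 with the genotype label cKO, a conditional knockout of Alyref. Total RNA was extracted with Trizol and libraries were made with an mRNA library preparation kit, per the labels' protocols. The strand setting of the kit and the type of read are not given in the sources used here, so reads of overlapping or antisense genes could not be told apart. Each sample took its group and its replicate number from its title. In the value columns 1 group is called Ctrl where the sample titles have WT, and those columns were matched to the WT samples with the same number, since the remaining columns carry the name cKO. The design text describes 4 rounds of sequencing on separate biological replicates, and no label says which sample belonged to which round, so batch effects could not be tested.

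The file held 18560 genes with symbols and Entrez identifiers, and 4 values per gene and library. Estimated counts per gene, deposited by the authors without scaling for depth, were not whole numbers for 10.3% to 11% of values, depending on the library. FPKM and TPM values were made by the authors, per the file headers. The authors' normalized counts, a signal given by the file headers without a method, equalled the estimated counts rounded up to whole numbers and multiplied by a constant in each of the 8 libraries, tested on genes with at least 10 estimated counts, over which the ratio ranged by less than 1e-09 of its median. That constant lay between 0.922 and 1.055. HISAT2 2.2.1, Bowtie2 2.4.5, RSEM 1.3.1 and the builds GRCm38 and mm10 are named in the submitters' processing notes, which give no role or order for them. The annotation and any filter applied before deposit are not given in the sources used here. Genes of the mitochondrial genome and Xist had no line in the table. RSEM shares reads that match several genes between them by estimation, which makes values of near-identical copies uncertain.

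Total estimated counts were 15522915 to 16482614 per library, so that depth differed little between libraries. Genes below 1 CPM rested on few counts and carried large counting error. Between 17142 and 17396 genes had a count in a library.

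Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes with low counts were removed with edgeR's filterByExpr by group, which left 15098 genes. TMM normalization and quasi-likelihood tests followed, with group as the only term. Adjusted p-values are Benjamini-Hochberg values over all tested genes, with a threshold of 0.05, and fold changes compare libraries labelled cKO with libraries labelled WT. Standard errors of log2 fold changes were taken from the fold change and the F statistic. Intervals of fold changes are at the 95% level. CPM values were computed with TMM-scaled totals of the tested genes. For Alyref and Ccn3 the difference of mean log2 CPM was also tested by exact permutation of the group labels over the 70 assignments, two-sided, for which the smallest p is 0.029.

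Gene lists were fixed before the data were examined. They covered mRNA export, the RNA 5-methylcytosine (m5C) machinery, the CCN family, cell types of the ganglion and of neighbouring tissue, and signalling and stress programmes, 34 in all. Of these, 32 had at least 5 tested members. The sex-linked list had 4 tested members and the mitochondrial genome list 0. The lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the 32 lists. Camera with an estimated correlation and fry were run beside it.

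The rule for named genes was also fixed before the data were examined. It took Alyref and Ccn3, then up to 12 genes in each direction with the largest fold change among those with adjusted p below the threshold, no overlap between groups and at least 1 CPM, and up to 6 such members of each list. Where fewer than 5 genes passed in a direction, the 8 genes of lowest p were given and said not to pass, which applied to both directions. Some genes that the rule takes are not reported here. Up to 3 members of lowest p were given for a list with no member past the threshold. Predicted genes were named only among the first 3 of a direction, and sex-linked genes were given only as a check of the libraries. Cell type markers whose range over libraries is given were picked from the fixed lists after the values were seen.

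Gene positions came from a RefSeq gene table of GRCm38.p6, the assembly named in the submitters' notes, matched by Entrez identifier for 18507 of 18560 genes and for 15065 of the tested genes. The similarity of libraries was checked with Spearman correlations, a principal component analysis and a chi-square test of the counts of each pair, which ranged from 3.56 to 108 per degree of freedom. All pairs therefore differed by more than sampling noise and each library was counted as 1 replicate.

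Alternatives covered DESeq2 size factors, upper quartile scaling, no filter and a stricter filter on low counts, the DESeq2 1.42.0 Wald test, limma-voom, and limma on log2(FPKM + 1) and log2(FPKM + 0.1). They also covered the replicate number as a block, a fold filter, 1 surrogate variable from sva 3.50.0, and leaving out each library in turn. After the data were seen, fits with covariates for tissue makeup, for the level of Ddx3y and for fibroblast genes were added. The tissue makeup covariate was the mean log2 CPM of nociceptor markers minus that of spinal cord markers. The median log2 fold change of all genes was −0.0048 with TMM scaling and −0.0198 with upper quartile scaling. Correlations and exact tests were computed in Python 3.11.15 with scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

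The test of genes was tested on simulated data, with counts drawn from the means, depths and dispersions of these libraries and 50 genes changed at each of several folds among 15004 genes in the fit. It recovered 0 of 50 genes at the smallest fold (25% up or the inverse), 22% of genes changed 1.5-fold, 62% of genes changed 2-fold and 96% of genes changed 4-fold, with 3 false calls in all. The dispersions used there included the spread added by WT replicate 2. In simulated data with 1 list of 32 shifted 1.5-fold, camera called that list and 0 others. Counts drawn from means, depths and dispersions carry no correlation between genes, while the estimated correlation reached 0.93 in the interferon response list. The 0 others therefore cannot show how often lists are falsely called here, where splits of the 8 libraries into 4 and 4 called 8 to 18 lists with the preset.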

Results

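Dorsal root ganglia hold the cell bodies of the sensory neurons that carry touch, temperature and pain signals from the body to the spinal cord. RNA sequencing of this tissue compared 4 mouse libraries labelled WT with 4 labelled cKO, a conditional knockout of Alyref, and every genotype label also carried P60. Alyref encodes an adaptor protein that loads mRNA onto the nuclear export machinery. The submitters' title ties its loss to inflammatory pain and to export of Ccn3 mRNA from the nucleus, so Alyref and Ccn3 were examined first. RNA was taken from whole tissue, and the values do not separate nuclear from cytoplasmic transcripts. Neither the cells in which the gene was deleted nor an inflammatory treatment is given in the labels. Total estimated counts were 15522915, 16311155, 16145201 and 16268160 in WT replicates 1 to 4 and 15763458, 15891481, 15934914 and 16482614 in cKO replicates 1 to 4. The design text speaks of 4 sequencing batches without assigning samples to them, so within-batch values could not be given.

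Alyref mRNA was at nearly the same level in both groups. The gene (Entrez 21681, chromosome 11, 120594504 to 120598399, GRCm38) stood at 22.04 ± 2.71 CPM in WT and 20.5 ± 0.946 CPM in the libraries labelled cKO (SD, n = 4 each). Single libraries held 20.9, 25.7, 19.4 and 22.2 CPM in WT and 21.65, 19.4, 20.1 and 20.7 CPM in cKO. The log2 fold change was −0.11 ± 0.097 (SE; adjusted p = 0.887, edgeR), with a 95% interval from −0.33 to 0.11. An exact permutation test of log2 CPM gave p = 0.37. The lower bound corresponded to 0.797 times the WT level, so a reduction of whole-tissue Alyref mRNA beyond that bound was outside the interval. Counts per gene do not show which part of the transcript was read, and a deletion limited to some of the cells would alter the tissue total by the share of those cells. Groups are therefore named by their labels.

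Ccn3 had the larger difference of both genes. Ccn3, which encodes a secreted matricellular protein of the CCN family (Entrez 18133, chromosome 15, 54745910 to 54753762, GRCm38), stood at 38.7 ± 26.7 CPM in WT and 17.2 ± 2.92 CPM in cKO (SD, n = 4 each). The WT libraries held 28.3, 78.2, 29.6 and 18.9 CPM, and the cKO libraries 17.4, 20.8, 16.9 and 13.6 CPM. The log2 fold change was −1.17 ± 0.41 (SE), or 0.443 times the WT level, with a 95% interval from −2.11 to −0.24 and an adjusted p = 0.887 (edgeR), so the gene did not pass the threshold over all genes. All 4 cKO libraries lay below the WT mean, while WT replicate 4 lay below cKO replicate 2, and an exact permutation test gave p = 0.057. The size depended on WT replicate 2. Without it the log2 fold change was −0.57 ± 0.17 (SE; adjusted p = 0.9997, edgeR). Over all alternative settings the log2 fold change lay between −1.40 and −0.41, with adjusted p from 0.421 to 0.9999. These adjusted values cover all tested genes. The unadjusted p of Ccn3 alone was 0.019 with all libraries, 0.0091 without WT replicate 2 and 0.087 with the fibroblast covariate (edgeR). An exact permutation test without WT replicate 2 gave p = 0.086, where the smallest possible is 0.029.

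The CCN family and its integrin receptors had 9 of 12 members lower in the libraries labelled cKO, with a median log2 fold change of −0.34. No member passed, whether adjusted over all genes or adjusted over the list alone (lowest value 0.106). Camera with the preset correlation gave adjusted p = 0.0261 for the list, and adjusted p = 0.751 with an estimated correlation. Ccn5 stood at 4.98 ± 2.24 CPM in WT and 2.05 ± 0.919 CPM in cKO, and Ccn2 at 43.6 ± 9.82 and 32.2 ± 4.89 CPM (SD, n = 4 each). The list mean of WT replicate 2 lay above those of the other 7 libraries, and without it the list median was −0.05.

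**Figure D1:**
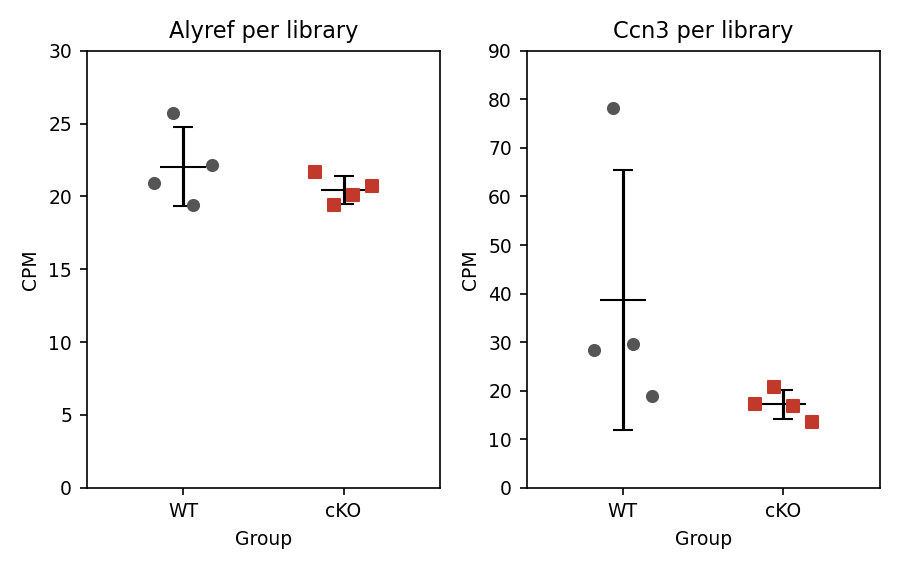
CPM of Alyref (left) and Ccn3 (right) in the 4 libraries labelled WT (circles) and the 4 labelled cKO (squares), with group means and SD as bars, on axes that start at 0. Alyref overlaps between groups, and Ccn3 ranges from 18.9 to 78.2 CPM in WT against 13.6 to 20.8 CPM in cKO.

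Over the whole transcriptome no gene differed between the groups at the threshold. Of 15098 tested genes 0 had adjusted p below 0.05 in the edgeR test, and the lowest adjusted p was 0.887. At an unadjusted p below 0.05 there were 249 genes, 60 higher and 189 lower in cKO, where 754.9 would be expected by chance. That count depended on single libraries: it was 813 without WT replicate 1, 606 without WT replicate 4, 163 without cKO replicate 1, 128 without cKO replicate 2 and 163 without cKO replicate 3. The balance of directions also moved, to 129 higher and 163 lower without WT replicate 2 and to 436 higher and 380 lower with a covariate for fibroblast genes. DESeq2 called 1 gene, Lztfl1, limma-voom called 0 genes, and limma on FPKM called 0 genes with the filter and 1, Cst12, without it. At an unadjusted p below 0.05 these tools had 308, 225, 224 and 358 genes. Cst12 fell outside the rule for named genes and is named after its value was seen. Groups did not overlap for 229 genes, or 1.52% of those tested, and chance gives 2.86%.

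The genes of lowest p among those lower in cKO included Lztfl1, 2010315B03Rik, Lars2, Igf1, Rpl31-ps12, Btg2 and Capn11, and none of them passed (adjusted p = 0.887 for each, edgeR). Lztfl1, which regulates protein traffic at the cilium, stood at 69.8 ± 4.50 CPM in WT and 54.2 ± 1.24 CPM in cKO, a log2 fold change of −0.37 ± 0.06 (SE). The predicted gene 2010315B03Rik stood at 20.2 ± 0.891 and 15.4 ± 0.231 CPM, and Lars2, the mitochondrial leucyl-tRNA synthetase, at 19.2 ± 1.53 and 14.5 ± 0.652 CPM (SD, n = 4 each). Each of these 3 genes was lower in every cKO library than in any WT library, and all 3 lay on chromosome 9. On GRCm38, Lars2 spans 123366927 to 123462675, Lztfl1 123694404 to 123717625 and 2010315B03Rik 124291802 to 124312719.

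Igf1, a growth factor, stood at 27.7 ± 9.69 CPM in WT and 14.3 ± 2.06 CPM in cKO, and Btg2, an antiproliferative early response gene, at 18.5 ± 3.77 and 12.6 ± 0.997 CPM (SD, n = 4 each). Both had groups that did not overlap. Capn11, a calcium-dependent protease, had log2 fold change −2.48 ± 0.67 (SE), with 8.70, 0.697, 5.67 and 7.66 CPM in the WT libraries against 1.01 ± 0.376 CPM in cKO (SD, n = 4). WT replicate 2 lay among the cKO libraries for this gene, and without it the log2 fold change was −2.85 with adjusted p = 0.041 (edgeR; 0.013 to 0.979 over the alternative settings). Rpl31-ps12 is a pseudogene of a ribosomal protein, and its 1.04 and 0.190 CPM may not be separable from those of other copies.

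The genes of lowest p among those higher in cKO were Duxbl2, Sec11c, P2rx6, Plekhf1, Hsd17b2, Pcdhga8, Plcd4 and Sphk2, and none passed (adjusted p = 0.887 for each, edgeR). Sec11c, a subunit of the signal peptidase, stood at 79.4 ± 4.54 CPM in WT and 96.6 ± 9.32 CPM in cKO. P2rx6, a subunit of ATP-gated channels, stood at 13.8 ± 1.37 and 17.1 ± 0.741 CPM, and Sphk2, a sphingosine kinase, at 25.4 ± 0.188 and 28.9 ± 1.70 CPM (SD, n = 4 each). The log2 fold changes of Plekhf1, Plcd4 and Hsd17b2, which oxidises sex steroids, were 0.35, 0.19 and 0.68. Duxbl2 was near the detection floor, at 0.0923 CPM in WT and 0.881 CPM in cKO, and it has close copies. Pcdhga8 (log2 fold change 0.31) belongs to a protocadherin cluster whose members share exons, so both values are uncertain.

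**Figure D2:**
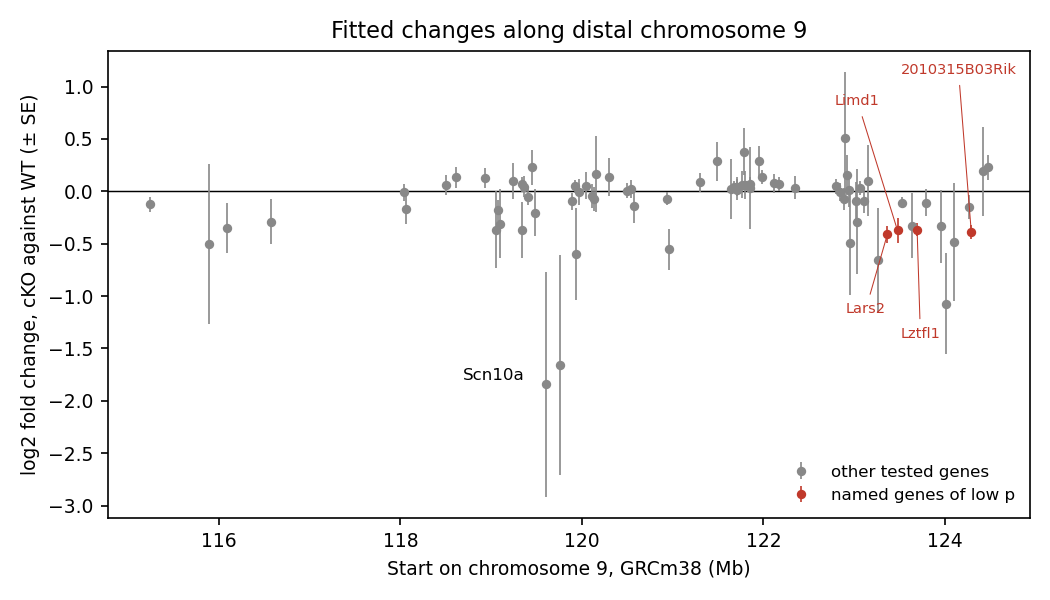
Log2 fold change of cKO against WT (vertical axis, bars are SE) for tested genes on the distal part of chromosome 9, without 1 gene not reported here, at their start in Mb on GRCm38 (horizontal axis). The 4 coloured genes, Lars2, Limd1, Lztfl1 and 2010315B03Rik, lie between 123.4 and 124.3 Mb with log2 fold changes from −0.41 to −0.37, while none passed the threshold over all genes; Limd1 was named after its position was seen.

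WT replicate 2 differed from the other 7 libraries in its cell type markers. Its 31 nociceptor markers averaged 4.99 log2 CPM against 2.67 to 3.77 in the others, and its 27 spinal cord markers averaged 5.31 against 6.20 to 6.45. Calca, the neuropeptide precursor of peptidergic pain neurons, reached 1044 CPM there and 69.3 to 291.4 CPM elsewhere. Scn10a, a sodium channel of nociceptors, reached 237.1 CPM against 3.76 to 53.9 CPM. Spearman correlations of WT replicate 2 with other libraries were 0.944 to 0.967, and those among the other 7 were 0.990 to 0.996. The first principal component carried 58.7% of the variance and set this library apart.

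All 8 libraries carried high levels of genes of the central nervous system. Slc1a2, the main glutamate transporter of astrocytes, lay between 878.4 and 2688 CPM, and Slc6a5, the glycine transporter of inhibitory spinal neurons, between 234.2 and 536.1 CPM. Gad1, which makes the transmitter GABA, lay between 115.9 and 260.8 CPM, and the oligodendrocyte genes Mog and Mobp between 86.5 and 358.8 and between 371.2 and 1460 CPM. Outside WT replicate 2, spinal cord markers averaged 6.20 to 6.45 log2 CPM and nociceptor markers 2.67 to 3.77. The sensory neuron gene Avil stood at 14.1 to 96.6 CPM there. These levels sit poorly with a label of dorsal root ganglia alone. Comparisons of the groups therefore hold for the tissue as sequenced, and not for ganglion cells alone. Mbp, a myelin gene of both Schwann cells and oligodendrocytes, was the top gene of each library, with 0.790% to 2.28% of counts. Y-linked transcripts were near 0 in WT replicates 1 and 2 and in cKO replicates 1 and 3, and Ddx3y stood at 92.5 to 117.5 CPM in the other 4 libraries.

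**Figure D3:**
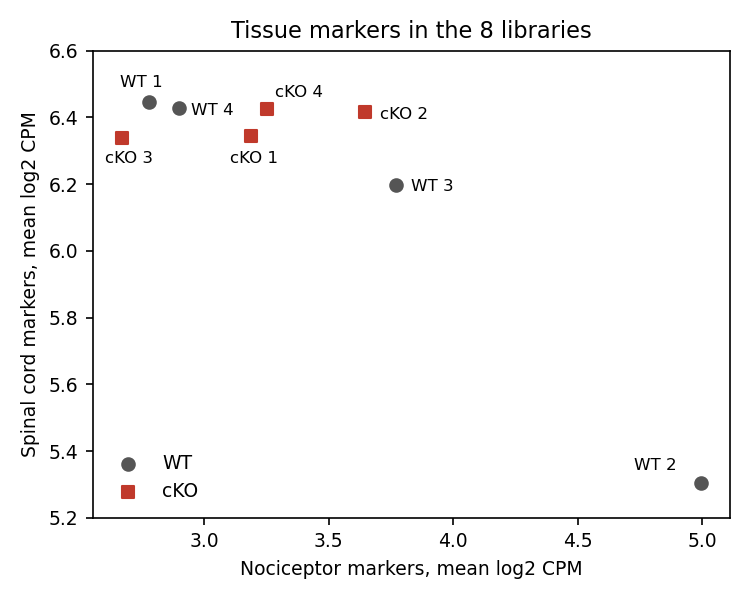
Mean log2 CPM of 31 nociceptor markers (horizontal axis) and of 27 spinal cord markers (vertical axis) in each library, WT as circles and cKO as squares. WT replicate 2 lies alone at 4.99 and 5.31, and the other 7 libraries lie between 2.67 and 3.77 on the horizontal axis and between 6.20 and 6.45 on the vertical axis.

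Markers of nociceptor types had lower means in cKO with WT replicate 2 included and nearly equal ones without it. The 17 tested markers of non-peptidergic nociceptors were lower in cKO for 16, with a median log2 fold change of −1.04, and 16 were at their highest in WT replicate 2. Without it the median was 0.00. Camera with the preset correlation gave adjusted p = 0.00664, and adjusted p = 0.751 with an estimated correlation. Il31ra, the interleukin 31 receptor of itch neurons, stood at 5.93 ± 6.92 CPM in WT and 1.71 ± 1.02 CPM in cKO, and Mrgpra3, another itch receptor, at 2.50 ± 3.56 and 0.664 ± 0.417 CPM (SD, n = 4 each).

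Peptidergic nociceptor markers had 11 of 14 members lower (median −0.49), among them Trpv1, the capsaicin receptor, at 23.7 ± 31.5 and 8.07 ± 4.16 CPM, and neurotrophic factor genes had 12 of 17 lower (median −0.20), among them Gfra3 at 6.66 ± 8.67 and 2.10 ± 1.28 CPM. Low-threshold C-fibre and cold neuron markers had 8 of 11 lower (median −0.26), and excitability channels 30 of 50 lower (median −0.04). None of these lists was called (adjusted p = 0.139, 0.447, 0.583 and 0.583 by camera), and their medians without WT replicate 2 were −0.01, 0.00, −0.01 and −0.04. Scn10a stood at 78.2 ± 107.8 CPM in WT and 21.8 ± 16.9 CPM in cKO (SD, n = 4 each).

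A-fibre markers had 18 of 23 members higher in cKO, with median log2 fold change 0.13 and mean −0.01, and camera called the list (adjusted p = 0.0261 with the preset, adjusted p = 0.751 with an estimated correlation). Etv1, a transcription factor of proprioceptors, stood at 86.0 ± 14.3 CPM in WT and 104.6 ± 5.88 CPM in cKO, while Runx3, another one, stood at 1.34 ± 1.06 and 0.552 ± 0.0952 CPM. Inhibitory receptors had 19 of 29 higher (median 0.10, adjusted p = 0.00664 with the preset and 0.751 with an estimated correlation), with Adora1 at 150.7 ± 39.7 and 181.3 ± 5.79 CPM (SD, n = 4 each). In both lists WT replicate 2 held the lowest mean, and without it the medians were 0.03 and −0.01. That library was lowest for 18 of the 23 A-fibre markers, although its nociceptor markers were high. The A-fibre list therefore cannot be read as ganglion neurons alone in these libraries.

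Pan-neuronal markers divided evenly, 10 higher and 10 lower (median −0.01), although camera ranked the list upward, and Avil, a sensory neuron gene, stood at 135.3 ± 178.7 and 47.4 ± 29.2 CPM. Synaptic release genes had 23 of 32 higher (median 0.07). Nerve injury genes had 17 of 31 lower (median −0.01, also ranked upward by camera), with Atf3, the standard marker of axotomy, at 3.59 ± 3.08 and 1.86 ± 0.568 CPM (SD, n = 4 each). These 3 lists had adjusted p = 0.653, 0.0869 and 0.901 and were not called. Without WT replicate 2 their medians were 0.03, −0.01 and 0.01. The log2 fold changes of Avil and Atf3 were −1.51 and −0.95 with all libraries and −0.01 and −0.16 without that library.

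Fibroblast and extracellular matrix genes had the lowest p of all lists. Of 40 tested members 37 were lower in the libraries labelled cKO, with a median log2 fold change of −0.66 and adjusted p = 1.35e-11 by camera with the preset, but adjusted p = 0.751 with an estimated correlation. Thbs1, a matricellular protein, stood at 67.0 ± 47.8 CPM in WT and 26.1 ± 8.39 CPM in cKO, and Igf2 at 175.0 ± 106.4 and 83.1 ± 15.3 CPM (SD, n = 4 each). WT replicate 2 held the highest value for 35 of the 40. Without that library 33 of 40 were lower, the median was −0.21, and adjusted p = 1.23e-06 with the preset, but adjusted p = 0.96 with an estimated correlation.

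Endothelial and mural markers had 23 of 28 members lower, a median of −0.22 and adjusted p = 9.64e-06 with the preset, against adjusted p = 0.751 with an estimated correlation. Myh11, the smooth muscle myosin, stood at 6.12 ± 1.70 and 3.82 ± 1.40 CPM, and Eng, an endothelial receptor, at 17.4 ± 3.96 and 12.9 ± 1.84 CPM (SD, n = 4 each). Without WT replicate 2, again 23 of 28 were lower and the median was −0.15. Immediate early genes, which respond within minutes to stimulation, had 28 of 29 lower (median −0.30), with adjusted p = 3.71e-06 with the preset and adjusted p = 0.751 with an estimated correlation. Fos stood at 28.4 ± 4.71 and 22.8 ± 1.51 CPM and Ier2 at 8.27 ± 2.28 and 5.89 ± 0.496 CPM. Without WT replicate 2 the median was −0.06 with 22 of 29 lower.

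Immune lists were lower in cKO with all libraries and near 0 without WT replicate 2. All 44 tested interferon response genes were lower (median −0.65, adjusted p = 2.78e-06 with the preset, adjusted p = 0.751 with an estimated correlation), and all 44 had their highest value in WT replicate 2. Ifit1 stood at 35.5 ± 34.9 and 14.1 ± 2.77 CPM (SD, n = 4 each), and the list median without that library was −0.06. Lymphocyte and granulocyte markers had 15 of 15 lower (median −0.64, adjusted p = 7e-04 with the preset, adjusted p = 0.751 with an estimated correlation), and the median without WT replicate 2 was 0.00. Cytokine and inflammation genes had 29 of 43 lower (median −0.18, adjusted p = 0.0261 with the preset, 0.751 with an estimated correlation), with Cxcl12 at 58.3 ± 12.9 and 44.3 ± 6.36 CPM, and a median of 0.02 without that library.

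Macrophage markers were not called with all libraries, with 26 of 32 lower (median −0.24, adjusted p = 0.237). The 6 members with higher means in cKO included Ctss, a lysosomal protease, at 91.2 and 107.4 CPM, and Csf1r, the macrophage growth factor receptor, at 86.7 ± 6.04 and 96.3 ± 1.10 CPM (SD, n = 4 each). Without WT replicate 2 the list was called higher (median 0.08, adjusted p = 0.00523 with the preset, adjusted p = 0.96 with an estimated correlation). Red blood cell genes had 9 of 10 lower (median −0.56, adjusted p = 0.00392 with the preset, adjusted p = 0.751 with an estimated correlation), and their median without WT replicate 2 was −0.20.

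Spinal cord markers were higher in the libraries labelled cKO for 26 of 27 members, with a median log2 fold change of 0.19. Camera gave adjusted p = 8.54e-06 with the preset and adjusted p = 0.751 with an estimated correlation. Olig2, a factor of the oligodendrocyte lineage, stood at 43.9 ± 15.8 CPM in WT and 59.3 ± 4.41 CPM in cKO, and Slc32a1, the vesicular transporter of GABA and glycine, at 103.5 ± 28.6 and 124.8 ± 7.01 CPM (SD, n = 4 each). WT replicate 2 was lowest for 25 of the 27, and without it the median was 0.05. Satellite glia markers had 16 of 23 higher (median 0.14, mean slightly below 0), and myelinating Schwann cell markers 12 of 22 lower (median −0.04), with Drp2 at 227.9 ± 90.4 and 154.9 ± 21.8 CPM. Muscle and fat genes had 10 of 17 higher (median 0.36), with means of 1.16 to 3.84 log2 CPM in single libraries. These 3 lists had adjusted p = 0.0979, 0.947 and 0.0946 and were not called. Without WT replicate 2 their medians were 0.03, 0.00 and 0.10, and the log2 fold change of Drp2 was −0.25, against −0.56 with all libraries. WT replicate 2 held the lowest mean of satellite glia markers (7.86 against 8.07 to 8.21 log2 CPM). With genes of the central nervous system high in all 8 libraries, the satellite glia and Schwann lists cannot be read as ganglion cells alone.

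Genes of mRNA export, the machinery in which Alyref acts, stood close together in both groups. Of 35 tested members 22 were higher and 13 lower, with a median log2 fold change of 0.02 and adjusted p = 0.573. Nup98, a nuclear pore component, stood at 42.5 ± 2.41 and 45.7 ± 2.77 CPM. The m5C machinery had 9 of 19 members higher (median −0.01, adjusted p = 0.948), with the methyltransferase Nsun2 at 82.7 ± 5.27 and 88.6 ± 2.03 CPM (SD, n = 4 each), and the m5C reader Ybx1 at 165.2 ± 47.5 and 143.7 ± 15.5 CPM. The log2 fold change of Ybx1 was −0.20 with all libraries and 0.02 without WT replicate 2. Camera ranked this list upward.

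Growth and metabolic lists divided. Ribosomal protein genes were lower for 81 of 82 (median −0.15, adjusted p = 1.37e-04 with the preset, adjusted p = 0.753 with an estimated correlation) and cell cycle genes for 25 of 25 (median −0.42, adjusted p = 2.68e-04, then 0.751). WT replicate 2 held the highest value for 80 of the former and for all 25 of the latter, and without it the medians were 0.06 and 0.05. Without it the ribosomal list was called in the opposite direction (adjusted p = 3.89e-07 with the preset, adjusted p = 0.96 with an estimated correlation). Mcm6, a replication helicase subunit, stood at 17.3 ± 7.31 and 13.1 ± 1.27 CPM (SD, n = 4 each). Oxidative phosphorylation genes had 44 of 81 higher (median 0.01, below 0 with upper quartile scaling, mean slightly below 0, adjusted p = 0.325), and without WT replicate 2 they were called higher (median 0.07, adjusted p = 3.89e-07 with the preset, adjusted p = 0.96 with an estimated correlation).

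The remaining lists were not called. Endoplasmic reticulum and integrated stress genes had 21 of 36 higher (median 0.02, mean −0.01, adjusted p = 0.285), with Herpud1 at 71.2 ± 3.94 and 80.3 ± 5.08 CPM. Genes of p53 and apoptosis had 27 of 37 lower (median −0.07, adjusted p = 0.16), with Trp53 at 24.7 ± 2.34 and 21.6 ± 1.53 CPM. Cholesterol synthesis genes had 14 of 23 lower (median −0.04, adjusted p = 0.583), and circadian clock genes 16 of 22 higher (median 0.04, adjusted p = 0.237), with Nr1d1 at 64.5 ± 8.96 and 59.1 ± 1.85 CPM (SD, n = 4 each). Without WT replicate 2 the medians of these lists, in the same order, were 0.03, −0.0035, 0.02 and −0.01, so the cholesterol and clock medians changed sign.

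Across the lists camera with the preset correlation called 14 of 32, 11 lower and 3 higher in the libraries labelled cKO. With an estimated correlation 0 were called, and fry called 0 (lowest adjusted p = 0.767). No member of any list passed when adjusted over the list alone. In all 14 called lists the mean of WT replicate 2 lay outside the range of the other 7 libraries, as it did in 29 of the 32. Without that library 6 lists were called with the preset, 3 lower and 3 higher, and 0 with an estimated correlation (lowest adjusted p = 0.96). With the preset only 3 were called both times in the same direction, namely fibroblasts and matrix, endothelial and mural cells, and immediate early genes.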

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

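The tests of tissue shares and of depth in WT replicate 2 were chosen only after the marker levels were seen.

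In 5 of 102 groups of 4 libraries a single library lay far from the other 3, where 5.1 would be expected by chance. On the log2 CPM scale, Hsd17b2 stood at 1.87 in cKO replicate 1 against 2.21 to 2.25 in the other cKO libraries. Capn11 stood at −0.81 in cKO replicate 2 against 0.33 to 0.46. Among list means, A-fibre neuron markers stood at 6.67 in WT replicate 2 against 6.87 to 6.91 in the other WT libraries, and genes of p53 and apoptosis at 4.35 in the same library against 4.08 to 4.12. Immediate early genes stood at 3.24 in cKO replicate 3 against 3.31 to 3.33.

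WT replicate 2 was also apart in its cell type markers, with high nociceptor and low spinal cord levels. The depth of the library was argued against as the cause, since its total of 16.31 M counts lay within the 15.52 to 16.48 M of the other libraries. Varying shares of ganglion and spinal cord tissue may underlie the pattern. In this library 25 of 27 spinal cord markers were at their lowest and 27 of 31 nociceptor markers at their highest. Of all 15098 tested genes, 5551 were at their lowest and 5665 at their highest there (12.5% by chance in either direction). Both directions together made 74.3% of tested genes (25% by chance). The median log2 difference from the other WT libraries was −1.08 for cord markers (interquartile range −1.54 to −0.65) and 2.02 for nociceptor markers. Other markers went both ways: list means in this library were above those of the other 7 for low-threshold C-fibre and cold neurons (4.61 against 3.39 to 3.93 log2 CPM), fibroblasts and matrix (6.46 against 4.95 to 5.53), macrophages (4.82 against 3.45 to 3.99) and pan-neuronal genes (8.27 against 7.67 to 8.07, with a median difference of −0.10 from the other WT libraries), and below them for satellite glia (7.86 against 8.07 to 8.21) and A-fibre neurons (6.67 against 6.82 to 6.94). Whether spinal cord also transcribes the latter markers was not tested, how the tissue was dissected is not given in the labels, and no biological explanation was tested.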

How the results depend on the processing

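The covariates for tissue makeup, Ddx3y level and fibroblast genes were chosen after the data were seen; the other alternatives were fixed before. The log2 fold changes of Alyref and Ccn3 kept their direction and stayed short of the threshold in 23 of 23 alternatives, from −0.17 to −0.0057 and from −1.40 to −0.41. Leaving out 1 library at a time gave −0.17 to −0.02 for Alyref and −1.40 to −0.57 for Ccn3, the latter without WT replicate 2. The number of genes past the threshold was 0, and it was 1 with the DESeq2 test (Lztfl1), 1 with log2(FPKM + 1) without a filter (Cst12), and 1 (Capn11) each with 1 surrogate variable, the tissue makeup covariate, makeup and Ddx3y together, and the fibroblast covariate. Leaving out single libraries gave 0 to 1 genes, the 1 being Capn11 without WT replicate 2. Gene lists called numbered 14, against 0 with an estimated correlation, 0 with fry, 6 with the makeup covariate, 6 with makeup and Ddx3y, 9 with the fibroblast covariate, and 6 to 18 with single libraries left out (6 without WT replicate 2, 18 without WT replicate 4). The cause was not tested. Of Alyref, Ccn3 and the ranked genes of lowest p none changed direction in the alternatives, and only Lztfl1 and Capn11 passed the threshold in any. Other list members were not followed over all alternatives. With the replicate number as a replicate block, 0 genes passed (213 at an unadjusted p below 0.05), 15 lists were called and Ccn3 had log2 fold change −0.98. Whether the numbers pair the samples stayed open. Same-numbered libraries had correlations of deviations from the group means of 0.0078, 0.045, −0.037 and 0.25, and 2 of 8 libraries correlated best with their own number. WT replicate 2 weighs heavily on the WT deviations, so this check cannot rule pairing out. Among WT and cKO pairs, WT replicate 4 and cKO replicate 4 had the highest Spearman correlation (0.996), while WT replicate 1 was nearest to cKO replicate 3 (0.9956). WT replicate 2 raised the common dispersion from 0.0104 to 0.0385.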

Other observations

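The tests of splits, of chromosome 9, of Scn10a against Scn11a, and of tissue makeup for Ccn3 were chosen only after the results were seen.

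Genes of low p gathered on distal chromosome 9, where 5 of the 50 genes of lowest p (among them Lars2, Limd1, Lztfl1 and 2010315B03Rik) lay between 123366927 and 124312719 on GRCm38. In that segment 12 of 12 tested genes had lower means in the libraries labelled cKO. The count includes those 5 genes, which also set the bounds, so it is partly fixed by their choice. The nearest tested genes outside were Tmem158 (log2 fold change −0.66) and Gm20783 (0.19). Unequal tissue makeup was argued against, since the median log2 fold change of the 5 was −0.396 with the makeup covariate. A linked chromosome segment that differs between the groups is a candidate explanation: as many as 5 in one 2 Mb span had permutation p = 4e-04 under shuffled positions (10000 permutations), and no other of the 35 splits gave more than 4. The segment starts 3.65 Mb from Scn10a (119608456 to 119719322), whose promoter is widely used to drive Cre in nociceptors, while the driver used here is not given in the labels. An allele at Scn10a may be part of it, since log2 Scn10a over Scn11a was 0.218 ± 0.152 in WT and −0.214 ± 0.319 in cKO (SD, n = 4 each). The difference was −0.431 (exact permutation p = 0.029, the smallest possible). Without WT replicate 2 the difference was −0.474 with all 4 cKO libraries still below every WT library (exact permutation p = 0.086 over 35 splits). Counts of Scn10a and Scn11a were only 60 and 95 in cKO replicate 3 and 126 and 116 in WT replicate 1. The ratios of WT replicate 2 and cKO replicate 2 lay close together, at 0.09 and 0.03, and that of WT replicate 1 was 0.12. Among tested genes between Scn10a and the segment, only Ulk4 (log2 fold change −0.55) had an unadjusted p below 0.05 (edgeR).

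Ccn3 had a lower mean in the libraries labelled cKO without passing the threshold, and the libraries differed in makeup. Tissue makeup, measured only as nociceptor minus spinal cord markers, was argued against as the whole cause. The log2 fold change was −0.621 ± 0.17 (SE) with that covariate, against −1.17 ± 0.41 without. That covariate mainly sets WT replicate 2 apart (−0.31 against −3.67 to −2.43) and does not measure fibroblast content, another part of the makeup. Fibroblast content may account for part or all of the lower Ccn3 mean. With the fibroblast covariate the value was −0.408 ± 0.214 (SE), between 1 and 2 SE from 0, so both stay open. Fibroblast genes also set WT replicate 2 apart (mean 6.46 against 4.95 to 5.53 log2 CPM). Without that library and no covariate the log2 fold change of Ccn3 was −0.57. Without WT replicates 2 and 3, Ccn3 and fibroblast genes had Pearson r = −0.06. Export of Ccn3 mRNA from the nucleus remains untested, because whole-tissue RNA does not separate nuclear from cytoplasmic transcripts. Whether the genotype lowers the level of Ccn3 stays open, since the difference did not pass the threshold. Alyref itself was at 0.928 times the WT level.

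Over 3 relations across the 8 libraries, Ccn3 followed fibroblast genes with Pearson r = 0.909 (permutation p = 0.0184, adjusted 0.0277) and Spearman rho = 0.50 (p = 0.216, adjusted 0.216, by permutation). It followed nociceptor markers with r = 0.815 (permutation p = 0.0343, adjusted 0.0343) and rho = 0.571 (p = 0.151, adjusted 0.216, by permutation). Nociceptor and spinal cord markers had r = −0.889 (permutation p = 0.0185, adjusted 0.0277) and rho = −0.571 (p = 0.151, adjusted 0.216, by permutation). Without WT replicates 2 and 3, r was −0.06, −0.199 and 0.159, so all 3 relations rest on those libraries.

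The real count of genes past the threshold was 0 by edgeR (249 at an unadjusted p below 0.05, and 1 by DESeq2 and 0 by limma-voom), which all 35 splits of the libraries reach by construction, so their number decides nothing. The highest other split, which parted the libraries by Y-linked transcripts, gave 5. For genes at an unadjusted p below 0.05, 25 of 35 splits reached the real 249, so chance could not be excluded. The highest other, 1349, came with WT replicates 1 and 4 and cKO replicates 1 and 3 on one side, several times the real count. Those libraries had the lowest means of nociceptor markers, 2.67 to 3.19 log2 CPM against 3.25 to 4.99 in the rest. That split therefore parted the libraries by nociceptor marker level, while the cause was not tested. For gene lists, 15 of 35 splits reached the real 14, and the highest other gave 18, so chance could not be excluded there either.

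Within 2 Mb of Alyref on chromosome 11, 34 of 70 tested genes had lower means in cKO and 2 had an unadjusted p below 0.05, the lowest being 0.00816 for B3gntl1.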
